A study of Bubalus bubalis with 8 samples.

How the data were processed

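RNA sequencing values were given for 8 libraries of water buffalo (Bubalus bubalis), 1 for each stage from the immature oocyte to the parthenogenetic blastocyst. The series describes the work as single-cell sequencing, but the number of oocytes or embryos in a library is not given in the sources used here. The extraction text attached to the samples names another tissue, so nothing about RNA isolation or library preparation was taken from it. Stage was taken from each sample's title, and each column was tied to its sample by the sample's description.

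The authors deposited a single table of FPKM values (fragment counts scaled by transcript length and by the mapped fragments of the library), per the file's name, with 28659 gene IDs and 8 library columns. The aligner, the assembler, the genome build, the annotation and the filters are not given in the sources used here. The values were not whole numbers. No ID was at 0 in every library (0 of 28659), so the table holds only IDs with a signal somewhere. FPKM is divided by transcript length, so the column sum is higher where short transcripts take more of the reads. The sums ran from 892286 in the 8-cell library to 2501133 in the morula library.

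The IDs are of 2 kinds. There are 18220 IDs made of the word gene and a number, called numbered IDs here, 33 of them with a suffix. The other 10439 are named as new genes by the authors and are called new-gene IDs here. No symbol, coordinate or description is paired with them in the table. A search of the gene IDs, locus tags, symbols, synonyms and accessions of a RefSeq table of the buffalo assembly NDDB_SH_1 found 0 matches among the 28659 IDs. A number in an ID was not taken as a position in any annotation. The 28 gene lists fixed for oocyte, embryo, imprinting, metabolic, cumulus, blood, sperm and retina genes therefore had 0 members found and were not scored. For the same reason the rule for named genes allowed at most 2 IDs per direction. These were the IDs with the greatest log2 difference between the GV oocyte and the blastocyst among IDs with at least 10 FPKM in the higher library.

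Depth could not be recovered. If low values were whole multiples of 1 read, the ratio of low values between a pair of libraries would repeat. Among IDs at 0.005 to 0.3 FPKM in both libraries of a consecutive pair and written with at most 6 significant digits, 1.55% to 9.35% lay within 0.01 log2 units of the commonest ratio. Read counts were thus not used, total depth is unknown, and no counting interval or floor is given. An exact 0 is reported only as a value listed at 0.

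Values were taken to log2(FPKM + 1), so folds of low IDs are understated. With 1 library per stage there is no replicate error and no test between a pair of stages. Stages were compared by a rule of size: an ID differed when its log2(FPKM + 1) values were 2 or more apart and the higher library had at least 10 FPKM. This was done for the GV oocyte against the blastocyst and for the 7 consecutive steps. Trajectory classes followed the same sizes. Maternal-high IDs had at least 10 FPKM in an oocyte library, and their lower oocyte value was at least 2 log2 units above the highest of the 16-cell, morula and blastocyst values. Embryo-high IDs had at least 10 FPKM in 1 of those 3 libraries, and the lowest of the 3 was at least 2 log2 units above both oocyte values. Single-stage IDs had 1 library with at least 10 FPKM that was at least 2 log2 units above each of the other 7. Steady IDs had at least 10 FPKM in every library and a range under 1 log2 unit. An ID was called detected at 1 FPKM or more.

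The order of the libraries was tested with a one-sided exact permutation (Mantel) test of the distance between libraries, 1 minus Pearson's r over IDs with at least 10 FPKM in any library, against the number of steps between stages, over all 40320 orders. A threshold of 0.05 was used. The rules, classes, test and alternative settings were fixed before the data were examined. The alternatives were a pseudocount of 0.1, no minimum or a minimum of 30 FPKM, rescaling of each library to a sum of 1000000 (as in TPM), median-of-ratios scaling, other detection thresholds, a rank distance and leaving out libraries. Restricting the counts to numbered IDs, leaving out libraries of a class, permuting within the sets of libraries and leaving out both end stages were added after seeing the data.

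The rule of size was tested on simulated data. GV values were compared with a copy that carried log-normal noise of SD 0.51 log2 units, the robust SD between the 4-cell and 8-cell libraries, and in which 200 of 28659 IDs were changed by a known fold. The rule recovered 34.5% of IDs changed 4-fold, 97.5% of those changed 8-fold and 100% of those changed 16-fold, with at most 2 false IDs. This noise was the lowest of the 7 consecutive steps, and the noise between replicates is unknown with 1 library per stage. With SDs of 0.83 and 1.03 log2 units, the robust SDs of the MII oocyte to 2-cell and of the GV to MII oocyte steps, the rule recovered 87.0% and 81.0% of IDs changed 8-fold and gave 90 and 384 false IDs (1.18% of 7653 and 4.88% of 7869 unchanged IDs compared). With an SD of 2.96, that of the 8-cell to 16-cell step, it recovered 61.5% and gave 5271 false IDs (54.7% of 9638 unchanged IDs compared). The false share was 7.75% with the SD of the 2-cell to 4-cell step (1.15). It was 38.9% with that of the 16-cell to morula step (2.15) and 11.2% with that of the morula to blastocyst step (1.26). These SDs include any differences between the stages. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.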

Results

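The transcriptome of buffalo oocytes and of embryos made by parthenogenetic activation, in which an egg develops without sperm, was followed over 8 stages. The stages were the GV oocyte (germinal vesicle, immature), the MII oocyte (metaphase II, mature), embryos of 2, 4, 8 and 16 cells, the morula and the blastocyst. The study asked how maternal transcripts, those laid down in the oocyte, change over this period. There was 1 library per stage, so no difference between a pair of stages had a replicate check, and the counts below describe these libraries. Sequencing depth is unknown, since only FPKM values were used. FPKM is relative to the rest of each library, so it does not give the amount of a transcript per oocyte or embryo. The table names no genes, and genes are therefore described as groups of IDs.

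Between 14078 and 16106 gene IDs were detected at 1 FPKM or more in each library from the GV oocyte to the 16-cell embryo, against 10677 in the morula and 11534 in the blastocyst. The highest number was in the 16-cell library, although at a threshold of 5 FPKM it had 8640 IDs and the GV oocyte 9397. Numbered IDs made up 11070 of those detected in the GV oocyte, 12003 in the 16-cell embryo, 9953 in the morula and 10853 in the blastocyst. Of the new-gene IDs, 4039 were detected in the GV oocyte and 4103 in the 16-cell embryo, but 724 in the morula and 681 in the blastocyst. New-gene IDs held 7.16% of the FPKM sum in the GV oocyte, 3.28% in the 16-cell embryo and 1.32% in the blastocyst. The share of IDs listed at exactly 0 was 21.8% in the GV oocyte, 18.4% in the 16-cell embryo, 48.7% in the morula and 45.7% in the blastocyst. The 100 most abundant IDs took 29.8% of the FPKM sum in the GV oocyte and 43.6% in the blastocyst. Of the 100 most abundant IDs of the GV oocyte, 64 were still among the top 100 in the 8-cell embryo, 24 in the 16-cell embryo and 16 in the blastocyst.

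**Figure D1:**
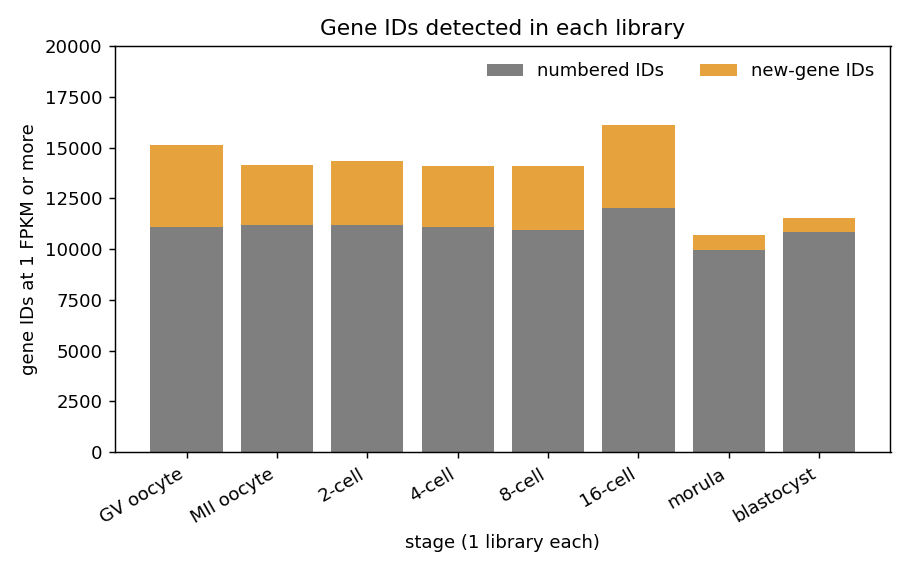
Gene IDs at 1 FPKM or more (y axis, number of IDs) in the library of each stage (x axis), with numbered IDs in grey and new-gene IDs in orange. Numbered IDs lay between 9953 and 12003 in all 8 libraries, while new-gene IDs were 724 in the morula and 681 in the blastocyst against 2990 to 4103 in the earlier libraries.

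The libraries fell into 2 sets. The GV, MII, 2-cell, 4-cell and 8-cell libraries resembled each other, with Pearson's r of log2(FPKM + 1) from 0.82 to 0.94 across the 11650 IDs with at least 10 FPKM in any library. The 16-cell library correlated with the 8-cell library at r = 0.51 and with the morula library at r = 0.69, and the morula and blastocyst libraries correlated at r = 0.88. These correlations are across genes, which are not independent replicates. With 1 library per stage, a change of stage between the sets cannot be told from a difference in how the libraries were prepared or processed. Within the first set, the 2-cell library was as close to the GV oocyte (r = 0.94) as to the MII oocyte (r = 0.93). The 8-cell library was closer than the 4-cell library to the GV oocyte (r = 0.85 against 0.82), the MII oocyte (r = 0.85 against 0.82) and the 2-cell embryo (r = 0.90 against 0.87), whereas the 4-cell library was closer to the morula (r = 0.42 against 0.39). The 16-cell library was closer to the 8-cell than to the 4-cell library (r = 0.51 against 0.47).

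Distance between libraries increased with the number of steps between their stages. The Mantel coefficient was 0.69 for Pearson's r and 0.74 for Spearman's rho over 8 libraries (exact permutation test over 40320 orders, one-sided p = 0.000446 for both). Without the GV and blastocyst libraries, the ends of the series, Pearson's r was 0.64 and Spearman's rho 0.72 (exact permutation p = 0.00556). Because the libraries formed 2 sets, the orders were also restricted to those that permute stages only within the 5 earlier and within the 3 later libraries, and the exact permutation p was then 0.0125 over 720 orders. Neither set holds 6 libraries, so no separate coefficient is given for either.

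**Figure D2:**
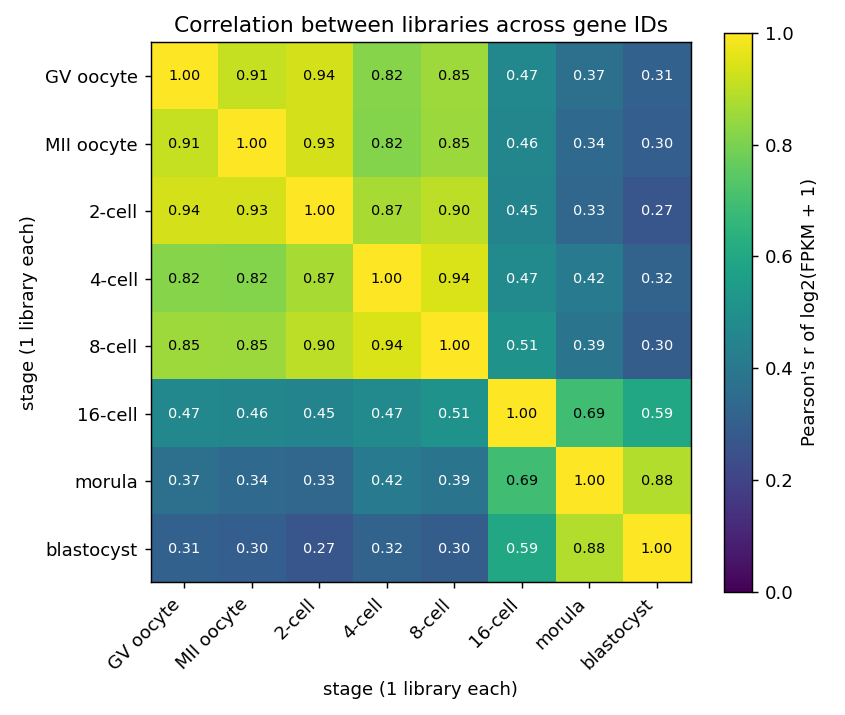
Pearson's r of log2(FPKM + 1) between each pair of libraries, across 11650 gene IDs, with stages on both axes and r as colour and number. The libraries from GV to 8-cell correlate at 0.82 to 0.94 with each other and at no more than 0.51 with the 16-cell, morula and blastocyst libraries.

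From the immature oocyte to the blastocyst, 59.1% of the compared IDs differed at least 4-fold on the log2(FPKM + 1) scale. Of 9235 IDs with at least 10 FPKM in either library, 3250 were lower and 2211 were higher in the blastocyst. New-gene IDs made up 920 of the 3250 lower IDs (28.3%) and 154 of the 2211 higher IDs (6.97%). They were 1149 of the 9235 IDs compared. The greatest increases were of gene13158, listed at 0 in the GV oocyte, at 173 FPKM in the 8-cell embryo, 5.18 FPKM in the 16-cell embryo, 199 FPKM in the morula and at 53665 FPKM in the blastocyst, and of gene29398, listed at 0 up to the 2-cell stage, at 478 FPKM in the 4-cell embryo, 7.72 FPKM in the 8-cell embryo and 22271 FPKM in the blastocyst. The greatest decreases were of gene13784, at 4089 FPKM in the GV oocyte, 54 FPKM in the 16-cell embryo and listed at 0 in the blastocyst, and of Bubalus_newGene_13792, at 7804 FPKM in the GV oocyte and 1.19 FPKM in the blastocyst. The balance depended on scaling. With each library rescaled to the same sum, which shifted the median difference by -0.75 log2 units, 3851 IDs were lower and 1181 higher. Median-of-ratios scaling, which shifted it by 0.22 log2 units, gave 2980 lower and 2494 higher. Among numbered IDs alone, 2330 were lower and 2057 higher.

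Transcripts of the GV oocyte were far below their GV level more often from the 16-cell stage on than in the earlier libraries. Of the 7124 IDs at 10 FPKM or more in the GV oocyte, 9.70% were under 25% of their GV value in the MII oocyte, 5.54% in the 2-cell embryo, 17.8% in the 4-cell embryo and 15.2% in the 8-cell embryo. The share was 43.8% in the 16-cell embryo, 44.5% in the morula and 47.2% in the blastocyst. Few of these IDs were below 0.1 FPKM at the 8-cell stage (0.267%), against 3.05% in the 16-cell embryo, 17.4% in the morula and 16.0% in the blastocyst. New-gene IDs, which were mostly undetected in the morula and blastocyst libraries, were 995 of the 7124. These shares do not tell a loss from transcripts missed in those libraries. Since FPKM is relative, they also do not tell a loss of a transcript from a gain of other transcripts, or show a loss shared by all.

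Maternal-high IDs, those at least 4-fold higher in both oocyte libraries than in the 16-cell, morula and blastocyst libraries, numbered 1664. Their median was 45.3 FPKM in the GV oocyte (interquartile range over IDs 20.6 to 123), 39.7 in the MII oocyte and 38.1 in the 2-cell embryo. It was 23.4 FPKM in the 4-cell and 24.9 FPKM in the 8-cell embryo, 2.20 FPKM in the 16-cell embryo and 0.079 FPKM in the morula. Together they held 31.4% of the FPKM sum in the GV oocyte and 1.92% in the 16-cell embryo. Between the MII oocyte and the 16-cell embryo, the steepest decrease was the step into the 16-cell stage for 1472 of the 1664 IDs (88.5%), the step into the 4-cell stage for 138 and the step into the 2-cell stage for 45. The class requires a low 16-cell value, which limits how late the decrease can come and leaves out IDs that fell only later. Without the 16-cell library the class held 2443 IDs. New-gene IDs made up 605 of the 1664 (36.4%), against 14.0% of all IDs at 10 FPKM or more in any library. New-gene IDs were also those mostly undetected in the morula and blastocyst libraries. Numbered IDs alone gave 1059 maternal-high IDs.

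Embryo-high IDs, at least 4-fold higher in the 16-cell, morula and blastocyst libraries than in both oocyte libraries, numbered 682. Their median was 1.68 FPKM in the GV oocyte, 2.20 FPKM in the 8-cell embryo, 57.7 FPKM in the 16-cell embryo and 86.2 FPKM in the morula. The greatest gain of 588 of them (86.2%) was the step into the 16-cell stage. It was the step into the morula for 58, into the 4-cell stage for 17 and into the blastocyst for 14. The class requires a high 16-cell value and so leaves out IDs that were first high in the morula or blastocyst, which limits how late the gain can come. The 2-cell, 4-cell and 8-cell values do not enter the class. Here too the timing rests on 1 16-cell library, and a difference of that library cannot be told from stage. New-gene IDs were 40 of the 682 (5.87%), against 14.0% of all IDs at 10 FPKM or more in any library. Without the 16-cell library the class held 1447 IDs, and with libraries rescaled to the same sum it held 401. A wider set of 1255 IDs was under 1 FPKM in both oocyte libraries and reached 10 FPKM later. The first library at 10 FPKM was the 2-cell embryo for 3 of these IDs, the 4-cell embryo for 133, the 8-cell embryo for 50, the 16-cell embryo for 513, the morula for 311 and the blastocyst for 245.

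**Figure D3:**
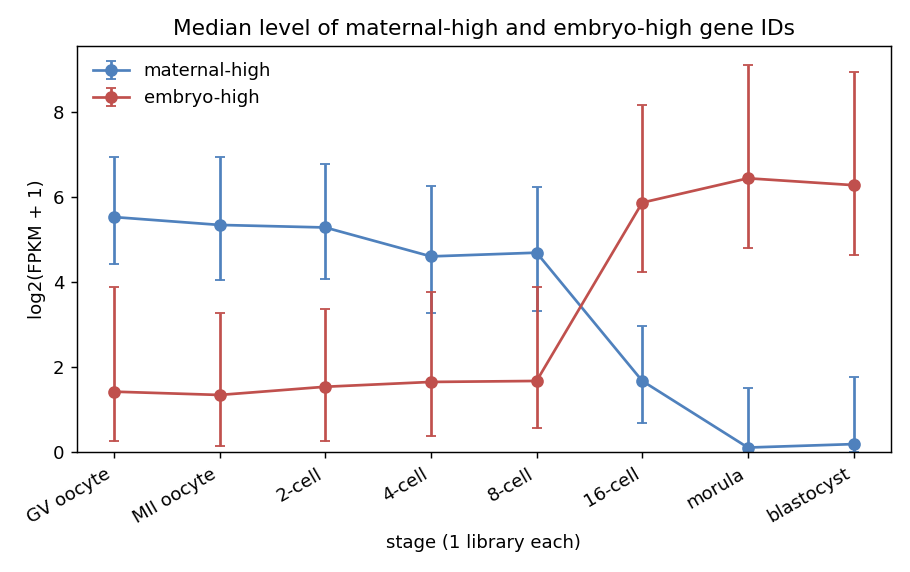
Median log2(FPKM + 1) (points) with the interquartile range over gene IDs (bars) of the 1664 maternal-high and 682 embryo-high IDs at each stage, 1 library per stage. The oocyte, 16-cell, morula and blastocyst values define the classes, while the 2-cell, 4-cell and 8-cell values do not. The maternal-high median was 5.53 at GV, 4.61 at 4-cell, 4.70 at 8-cell and 1.68 at 16-cell, and the embryo-high median was 1.42 at GV, 1.68 at 8-cell and 5.87 at 16-cell.

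The step from the 8-cell to the 16-cell embryo held the most differences of the 7 consecutive steps. Of 8657 IDs compared, 2080 were higher and 2351 lower in the 16-cell library, together 51.2%. With 1 library per stage, this does not tell a change of stage from a difference of the 16-cell library. The robust SD of the log2 difference was 2.96, against 0.51 for the 4-cell to 8-cell step, where 81 IDs were higher and 153 lower (3.19% of 7346). Simulated noise with an SD of 2.96 alone put 54.7% of unchanged IDs past the rule. The count at this step therefore does not separate differences between the stages from noise. New-gene IDs differed more often than numbered IDs at each of the 7 steps, with 79.0% against 47.7% here, 6.42% against 2.79% from the 4-cell to the 8-cell embryo and 74.7% against 34.4% from the 16-cell embryo to the morula. The balance of higher and lower IDs was not stable. With libraries rescaled to the same sum, 1683 IDs were higher and 2908 lower in the 16-cell library, whereas more were higher than lower with median-of-ratios scaling (2333 against 2137) and with no FPKM minimum (3377 against 3161).

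The earlier steps were smaller. During maturation from the GV to the MII oocyte, 594 IDs were lower and 216 higher (10.2% of 7973), and 170 of the 594 lower IDs were new-gene IDs (28.6%). New-gene IDs were 1083 of the 7973 IDs compared. From the MII oocyte to the 2-cell embryo, the step that holds activation and the first cleavage, 172 IDs were lower and 170 higher (4.35% of 7857). That balance followed the scaling, with 126 lower and 265 higher after rescaling to the same sum and 208 lower and 135 higher after median-of-ratios scaling. From the 2-cell to the 4-cell embryo, 471 IDs were lower and 333 higher (9.95% of 8081).

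From the 16-cell embryo to the morula, 1482 IDs were higher and 1406 lower (37.3% of 7742), and 301 of the lower IDs were new-gene IDs. New-gene IDs were 550 of the 7742 IDs compared. The balance turned with the scaling and with the FPKM minimum. There were 606 higher and 2070 lower after rescaling to the same sum, which shifted the median by -0.67 log2 units, 1202 higher and 1713 lower after median-of-ratios scaling, 1731 higher and 3118 lower with no minimum, and 1099 higher and 654 lower with a minimum of 30 FPKM. From the morula to the blastocyst, 807 IDs were higher and 453 lower (17.9% of 7050). With median-of-ratios scaling these were 976 and 301, and after rescaling to the same sum 546 and 212.

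**Figure D4:**
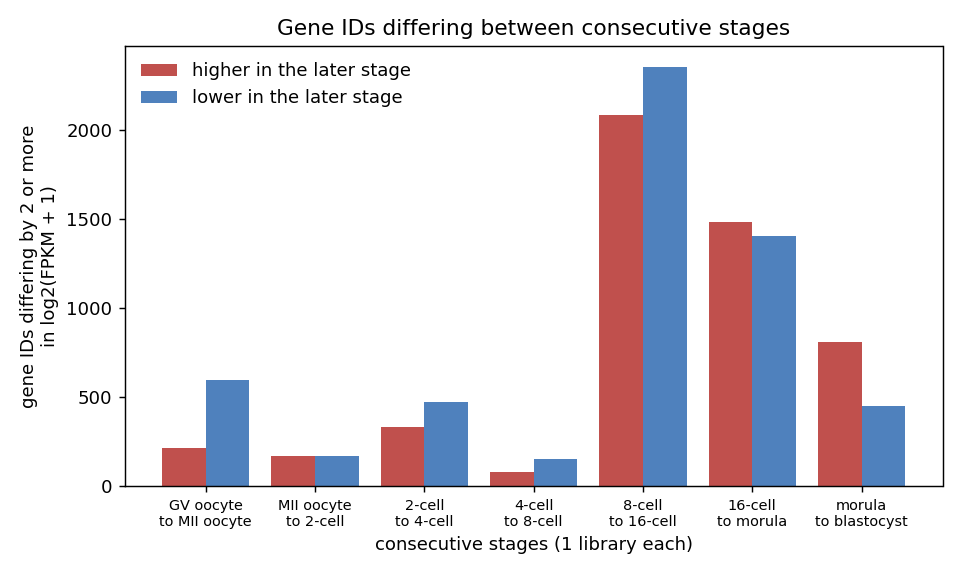
Gene IDs (y axis, number) that differed by 2 or more in log2(FPKM + 1) at each consecutive step (x axis), higher in the later stage in red and lower in blue, 1 library per stage. The 8-cell to 16-cell step has 2080 higher and 2351 lower IDs, and the 4-cell to 8-cell step 81 and 153.

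Single-stage IDs, at least 4-fold higher in 1 library than in each of the other 7, numbered 1059. The 16-cell library had 456 of them and the blastocyst library 378, while the morula had 83, the GV oocyte 48, the 4-cell embryo 36, the MII oocyte 35, the 8-cell embryo 19 and the 2-cell embryo 4. New-gene IDs were 36.0% of the 16-cell set and 8.47% of the blastocyst set. Of all IDs at 10 FPKM or more, they were 434 of 6266 in the 16-cell library and 219 of 6060 in the blastocyst library. Without the morula library, 1786 IDs were single-stage. The order of the 16-cell and blastocyst sets depended on the settings. After rescaling to the same sum the 16-cell set held 528 IDs and the blastocyst set 217, but with a minimum of 30 FPKM they held 228 and 251, and among numbered IDs alone 292 and 346. Steady IDs, at 10 FPKM or more throughout with a range under 1 log2 unit, numbered 25, and leaving out the GV, MII, 4-cell, 16-cell, morula or blastocyst library gave 46, 43, 43, 91, 65 or 101.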

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

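Restricting counts to numbered IDs, leaving out libraries of a class, permuting within the sets of libraries and leaving out both end stages were chosen after seeing the data; the other alternatives were planned. The Mantel coefficient stayed positive and past the threshold under all alternatives run (0.59 to 0.83). No count with a pseudocount of 0.1 moved by over 1.5 times. The cause of the other moves was not tested, except that a higher minimum or detection threshold leaves fewer IDs and no minimum more. With no minimum, IDs lower in the blastocyst than in the GV oocyte were 4932, the 2-cell to 4-cell step had 521 higher, the 4-cell to 8-cell step 152 higher and 282 lower, the 8-cell to 16-cell step 3377 higher, the 16-cell to morula step 3118 lower, and the morula to blastocyst step 1275 higher; single-stage IDs were 1801 and steady IDs 5428. With a minimum of 30 FPKM, 2009 IDs were lower in the blastocyst than in the GV oocyte; the consecutive steps had 109 higher (GV to MII), 89 higher and 100 lower (MII to 2-cell), 184 higher and 253 lower (2-cell to 4-cell), 46 higher and 75 lower (4-cell to 8-cell), 1301 higher and 1454 lower (8-cell to 16-cell), 654 lower (16-cell to morula), and 436 higher and 265 lower (morula to blastocyst). Single-stage IDs were then 604 and steady IDs 12. Rescaling each library to the same sum gave 1181 IDs higher in the blastocyst than in the GV oocyte, 265 higher from MII to 2-cell, 606 higher from 16-cell to morula, 212 lower from morula to blastocyst and 401 embryo-high IDs. Median-of-ratios scaling gave 301 lower from morula to blastocyst and 42 steady IDs. Numbered IDs alone gave 1059 maternal-high IDs. At 5 FPKM the IDs detected were 9397 in GV, 9040 in MII, 9353 in 2-cell, 8880 in 4-cell, 8789 in 8-cell and 8640 in the 16-cell library, so the 16-cell library did not have the most at that level. Leaving out a library of the class in turn gave 788 (without the morula) to 1447 (without the 16-cell library) embryo-high IDs, 794 (without the 16-cell library) to 1786 (without the morula) single-stage IDs and 29 to 101 steady IDs. The alternatives planned for gene lists were not run, as no list member could be matched. Depth is unknown, so how far low values are limited by counting cannot be given.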

Other observations

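The tests of numbered IDs detected in the morula, of IDs under 1 FPKM in the 16-cell library and of a mixture in the 16-cell library were chosen after the result was seen. The checks of other orders of the libraries had no prediction written beforehand. The remaining tests in this part were written before their results. With the 4-cell and 8-cell libraries exchanged, the Mantel coefficient of stage order was 0.70 against 0.69 as labelled, and the best of all orders (MII, 2-cell, GV, 8-cell, 4-cell, 16-cell, morula, blastocyst) also had 0.70, so the coefficient does not resolve the order within the 5 earlier libraries.

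The 16-cell library had the most IDs detected at 1 FPKM and, by the rule used, the most single-stage IDs (456 of 1059), although the blastocyst had more with a minimum of 30 FPKM (251 against 228) and among numbered IDs alone (346 against 292). As the source of the single-stage IDs, which reach 10 FPKM, only a background even enough to lift nearly all numbered IDs is argued against. In this library 34.1% of the numbered IDs were under 1 FPKM, which restates the number detected. That share was nevertheless the lowest of the 8 libraries (38.5% to 45.4% in the others). A background uneven over genes was not tested and stays open. For the wider detection of low IDs a background stays open. Of the 2708 IDs under 0.1 FPKM in the other 7 libraries, 86.8% (2350) reached 0.1 FPKM here. The same measure gave 24.0% to 49.4% in the other libraries. The IDs that did not reach it were the same 358 for every library, those under 0.1 FPKM in all 8. The share thus restates how many IDs reached 0.1 FPKM in 1 library only, and it does not measure how evenly silent IDs were lifted. The table also lists only IDs with some signal, which itself raises these shares. A mixture of 8-cell-like and morula-like RNA was not decided either. A mixture alone holds no ID above both of its parts, but the noise between replicates is unknown. Of the IDs at 10 FPKM or more, 11.6% (728 of 6266) lay at least 4-fold above both neighbours. This share was 0.517% to 2.30% in the MII, 2-cell, 4-cell, 8-cell and morula libraries. The 456 single-stage IDs among the 728 meet this by definition, so the share is no separate test of them. Of the numbered IDs at 1 FPKM or more, 5.02% (602 of 12003) were under 0.1 FPKM in both neighbours. That lies within sampling error of the bound of 5% set after the data were seen. The same share was 0.274% to 1.03% in the MII, 2-cell, 4-cell, 8-cell and morula libraries. Transcription particular to this stage is open too and was not tested, as there is 1 library.

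New-gene IDs were mostly undetected in the morula and blastocyst libraries. IDs at 10 to 30 FPKM in the 16-cell library were compared. Of these, 45.5% of 288 new-gene IDs and 5.60% of 2520 numbered IDs were under 0.1 FPKM in the morula, a ratio of 8.13. At 30 to 100 FPKM the shares were 31.9% of 91 new-gene IDs and 2.29% of 1793 numbered IDs. At 100 to 300 FPKM they were 15.8% of 38 and 1.38% of 869. In the blastocyst they were 54.2% and 5.44% at 10 to 30 FPKM, and 18.4% and 1.38% at 100 to 300 FPKM. The gap thus held at higher levels, although the new-gene share was lower there. These shares do not decide whether lower depth of the morula library alone is the cause. At equal FPKM a shorter transcript has fewer reads, and transcript lengths are unknown. Of the 434 new-gene IDs at 10 FPKM or more in the 16-cell library, 164 were single-stage there. Those are at least 4-fold lower in the morula by definition. Some transcripts may have been missed in the morula library, as 0.936% of IDs at 5 FPKM or more in both neighbours (55 of 5876) were under 0.1 FPKM there, against at most 0.148% in the MII to 16-cell libraries, a measure that leaves out IDs low in the 16-cell or blastocyst library. In the morula the difference was not in new-gene IDs alone. Numbered IDs detected there (9953, or 89.5% of the median of the 6 earlier libraries) were fewer than in each of the other 7 libraries (10853 to 12003). In the blastocyst it was mostly in new-gene IDs, which were at 21.8% of their median in the 6 earlier libraries, against 97.6% for numbered IDs. Besides lower depth, other explanations stay open and were not tested. New-gene models may have been assembled mainly from the earlier libraries, the late libraries may have been prepared or processed differently, or these transcripts may belong to the oocyte.

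The MII library had 594 IDs at least 4-fold lower than the GV oocyte. In the 2-cell library 30.3% of these were back within 1 log2 unit of their GV value, against 2.91% to 15.0% for the IDs lower at each of the 5 next steps, which were chosen in the same way. On the other hand 21.7% stayed at least 4-fold below GV in the 2-cell, 4-cell and 8-cell libraries. The median difference from GV was -2.50 log2 units at MII and -1.44 at the 2-cell stage. These values do not decide between low values in the MII library alone and a lasting loss. IDs chosen for a low MII value tend to lie nearer GV in the next library through noise alone. The noise between replicates is unknown, and the 2 explanations cannot be told apart for single IDs with 1 library per stage.

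A hypothesis was that numbered IDs with nearby numbers differ alike between the GV oocyte and the blastocyst, as they might if the numbers follow a position. Spearman's rho across pairs of IDs with consecutive numbers was 0.17 (4243 pairs, one-sided permutation p = 0.0001, the smallest that 10000 random orders can give, adjusted p = 0.0002 over 8 distances tested; highest random value 0.058). It was 0.12 at a distance of 2, 0.042 at a distance of 10 (adjusted permutation p = 0.007), 0.022 at a distance of 20 (adjusted permutation p = 0.1), 0.049 at a distance of 50 (adjusted permutation p = 0.004) and -0.03 at a distance of 100. Genes are not independent replicates, and reads shared between neighbouring copies of a gene may contribute to the value at a distance of 1.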
